A study of Mus musculus with 20 samples.

How the data were processed

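Poly(A) mRNA of mouse brown adipose tissue was sequenced in 20 libraries, 5 for each combination of genotype (wild type or adipose-specific CEBPB knockout) and temperature (room temperature or 4 h of cold). Per the labels' protocols, RNA was isolated with a PureLink kit and libraries were made with a KAPA stranded mRNA kit. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.0 and aligned with STAR 2.7.8a to the mouse genome GRCm38. The annotation release was not stated.

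The deposited values are counts, whole numbers of reads per gene in the layout that STAR writes, with 1 table per library and columns for both strands together, the forward strand and the reverse strand. Each table held 55471 gene IDs and 4 further entries that name no gene. Those entries count unmapped reads (3.86% to 5.66%), reads at several places (18.3% to 21.4%), reads in no gene (3.14% to 4.55%) and reads in more than 1 gene (1.02% to 1.16%). The reverse strand held 94.5% to 95.7% of the stranded gene counts and was used, which gave 27.07 to 55.18 M counts per library. Mitochondrially encoded genes took 28.8% to 36.0% of them. Of the IDs, 55144 had a symbol, 107 symbols occurred more than once, and 55230 IDs matched GENCODE M21 without the version. No column belonged to no sample. No 2 libraries were the same: within groups, pairs differed by 15.2 to 107.7 times counting error, as chi-square per degree of freedom. All libraries had the Y-linked expression of males, and so a fit with sex as a term was not run.

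Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr by group (count minimum 10, total minimum 15), which left 15233. Libraries were scaled by TMM, and 1 robust quasi-likelihood fit of the 4 groups with 16 residual degrees of freedom gave the 5 comparisons: cold in WT, cold in KO, knockout at RT, knockout in the cold and their interaction. P values were adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. The biological coefficient of variation was 15.3%. Values in CPM are means with SD over libraries, and log2 CPM used a prior count of 2. Principal components were computed on log2 CPM. Library measures were compared by exact 2-sided permutation tests over all 126 splits of 10 libraries, adjusted by Benjamini-Hochberg over 80 tests.

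Samples, comparisons, alternatives, gene lists and the rule for naming genes were fixed before the data were examined. Named genes were Cebpb and Cebpa, leading genes, and members of the lists. Leading genes were the 10 of largest change in each direction (5 for the interaction) among the genes that met all conditions. The conditions were passing the test, a mean of at least 5 CPM in a compared group and a symbol that does not mark a predicted gene. Outside the interaction, the 5 and 5 libraries compared also had to show no overlap. Genes outside this rule were chosen after their values were seen, and the text says so where they appear.

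The 31 lists were thermogenic and brown adipocyte genes, cAMP-responsive immediate early genes, secreted factors of brown fat, lipolysis and fatty acid uptake, fatty acid oxidation, fatty acid and triglyceride synthesis, cholesterol synthesis, glucose uptake and glycolysis, TCA cycle, nuclear-encoded respiratory chain, mitochondrially encoded respiratory chain, C/EBP family and adipogenic transcription factors, mature adipocyte genes, unfolded protein response, cytosolic and mitochondrial heat shock proteins, circadian clock, hypoxia and angiogenesis, acute phase and inflammatory genes, glucocorticoid-responsive genes, cell proliferation and extracellular matrix. The others were markers of macrophages, neutrophils, lymphocytes, endothelial cells, smooth muscle and pericytes, fibroblasts and adipocyte progenitors, skeletal muscle, white adipocytes, Schwann cells and nerve, and erythrocytes. Lists with at least 5 tested members (30 lists) were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists of a comparison, and again with the correlation estimated from the residuals. Members were also adjusted over the list alone.

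The alternatives were relative log expression normalization, no expression filter, the Wald test of DESeq2 1.42.0 without independent filtering, a fit of only the groups compared, the replicate number as a block, counts of both strands, each library left out in turn, and the skeletal muscle marker mean as a term. After the data were seen, 1 alternative was added, with both intermediate WT libraries left out. A fold against a group with 0 counts was taken against a floor of 3 counts over the group. Up to 100 splits of the libraries were refitted for each comparison.

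The procedure was tested on simulated data with the dispersion and depth of these libraries. Of genes changed 2-fold, it called 68.7% for cold in WT, 71.6% for cold in KO, 71.6% for the knockout at RT, 77.6% for the knockout in the cold and 59.7% for the interaction. Of genes changed 1.5-fold it called 61.2%, 61.2%, 52.2%, 64.2% and 19.4%. Between 4 and 10 of 14778 to 14814 unchanged genes were called, the changed list was called in all 5 comparisons, and 0 of 29 unchanged lists were. Genes were simulated independently of each other, so the list outcome does not carry over to lists whose members are correlated. For each fold 66 or 67 genes were changed, far fewer than the real cold comparisons called.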

Results

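Stranded mRNA sequencing was done on mouse brown adipose tissue (BAT), the fat depot that burns fuel for heat. The mice were wild type (WT) or carried an adipose-specific knockout (KO) of CEBPB, the transcription factor C/EBP beta, and were kept at room temperature (RT) or stressed by cold for 4 h. Each of the 4 groups held 5 libraries, 20 in all. Between 27.07 and 55.18 M reads per library were assigned to genes on the strand of the library kit, and 15233 genes passed the expression filter. Values are CPM, gene counts scaled to library size, as mean ± SD over the 5 libraries of a group, and changes are log2 fold changes ± SE. The labels do not state that the libraries come from separate animals, so each p measures the spread between libraries, which can be technical, and floors cover counting error only.

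The first principal component of log2 CPM held 53.9% of the variance and separated cold from RT in both genotypes. WT_RT replicate 4 (-23.4) and WT_cold replicate 5 (26.6) lay nearer the middle of this axis than the other libraries of their groups. The second component, with 7.82% of the variance, separated the genotypes, with means of -12.9 in WT_RT and 14.1 in KO_RT (exact 2-sided permutation p = 0.00794, n = 5 per group, adjusted p = 0.0706). That p is the smallest that 5 against 5 libraries allow, and none of the 80 tests of library measures passed after adjustment. The adjustment left little room to pass: the first component, which separated the temperatures, also had adjusted p = 0.0706 for cold in both genotypes. Not passing is thus no sign that groups were alike in a measure. Skeletal muscle markers, a sign of muscle in the sample, had a mean log2 CPM of 2.42 ± 3 in WT_RT, -0.861 ± 1.52 in WT_cold, 3.12 ± 1.72 in KO_RT and -1.77 ± 0.112 in KO_cold. Lymphocyte markers averaged -1.26 in WT_RT, -2.10 in WT_cold, -1.16 in KO_RT and -2.02 in KO_cold.

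**Figure D1:**
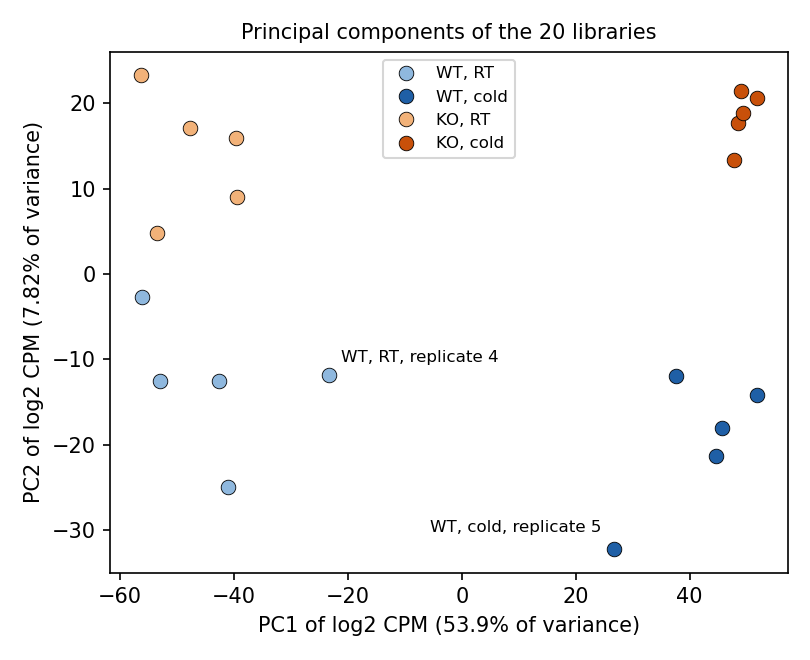
First against second principal component of log2 CPM, 1 point per library, coloured by group; the axes give the share of variance. The first axis, 53.9% of the variance, separates RT from cold, with WT_RT replicate 4 at -23.4 and WT_cold replicate 5 at 26.6.

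The targeted gene was nearly absent from all KO libraries. Cebpb (ENSMUSG00000056501.3, GRCm38 chromosome 2, 167688915 to 167690418) stood at 105 ± 19.9 CPM in WT_RT and 143 ± 22.4 in WT_cold. In the knockout it stood at 0.564 ± 0.253 CPM at RT and 1.92 ± 0.277 in the cold. The single WT libraries ranged from 75.5 to 167 CPM and the single KO libraries from 0.208 to 2.27 CPM. The knockout changed Cebpb by -7.53 ± 0.226 at RT (adjusted p = 5.62e-14) and by -6.23 ± 0.201 in the cold (adjusted p = 2.04e-13). Cold raised Cebpb by 0.46 ± 0.149 in WT (adjusted p = 0.0133) and raised the residual signal in KO by 1.75 ± 0.268 (adjusted p = 1.49e-05). The WT call ended with the skeletal muscle marker mean as a term (adjusted p = 0.127).

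Cebpa (ENSMUSG00000034957.10, GRCm38 chromosome 7, 35119293 to 35121928), the C/EBP family member that the series title names, was intact in the knockout. It stood at 526 ± 41.2 CPM in WT_RT and 520 ± 35 in KO_RT, a difference of -0.01 (adjusted p = 0.991). Cold lowered Cebpa by a log2 change of -1.99 ± 0.237 in WT (adjusted p = 1.34e-06), to 133 ± 74.2 CPM, and of -2.34 ± 0.24 in KO (adjusted p = 1.97e-07), to 103 ± 12.2 CPM. In the cold the knockout differed from WT by -0.37 in Cebpa (adjusted p = 0.417).

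**Figure D2:**
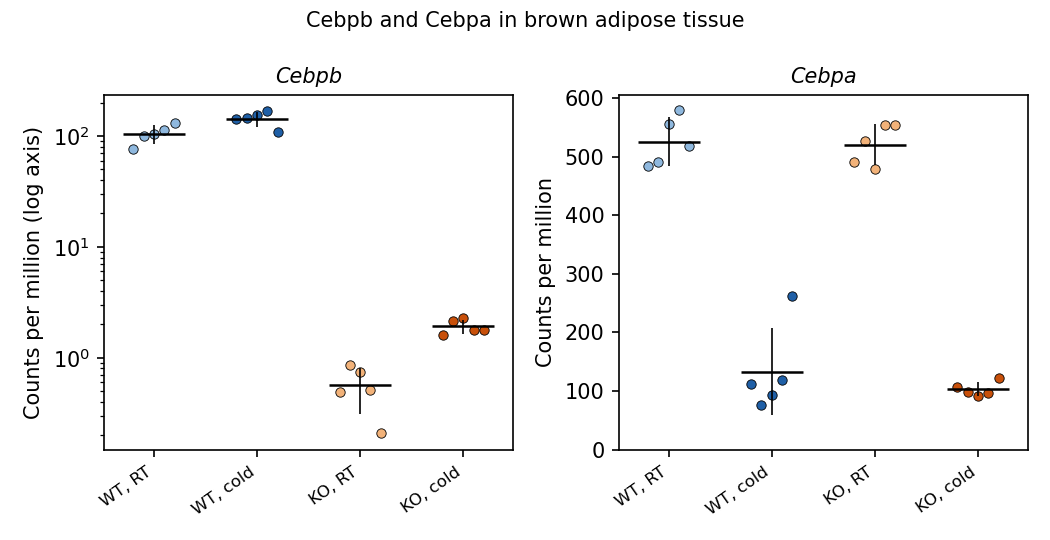
Cebpb (log axis) and Cebpa in CPM for the 4 groups; points are libraries, horizontal lines are group means and vertical lines are 1 SD. Cebpb is at most 2.27 CPM in every KO library and at least 75.5 CPM in every WT library, and Cebpa falls from 526 to 133 CPM in WT and from 520 to 103 CPM in KO.

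The comparison of WT_cold with WT_RT asks how normal brown fat responds to 4 h of cold. Ucp1, the uncoupling protein that makes heat, rose from 6372 ± 1379 to 11989.9 ± 866 CPM (0.91 ± 0.116, adjusted p = 8.27e-07). Dio2, the deiodinase that activates thyroid hormone, rose from 307 ± 70.7 to 3673 ± 734 CPM (3.58 ± 0.284, adjusted p = 1.11e-08), and Ppargc1a, a coactivator of mitochondrial genes, rose by 3.24 ± 0.307 (adjusted p = 1.03e-07). Mfsd2a, a lysophospholipid transporter, rose 47.2-fold from 2.29 ± 1.06 to 108 ± 17.8 CPM (adjusted p = 1.41e-06). Hmox1, heme oxygenase, rose 24.9-fold from 9.73 ± 2.57 to 243 ± 63 CPM (adjusted p = 3.39e-09). For these 5 genes all 5 WT_cold libraries lay above all 5 WT_RT libraries. The rule for leading genes required this of Mfsd2a, Hmox1 and Dio2. In all, 3997 genes rose and 4597 fell, 56.4% of those tested, of which 642 rose and 1339 fell at least 2-fold.

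The other leading genes that rose in WT were the acyl-CoA thioesterase Acot5 (5.33), the potassium channel subunit Kcne4 (4.77), the nuclear receptor Nr4a3 (4.35), the diacylglycerol kinase Dgkg (3.93), the stress factor Atf3 (3.87), the heat shock protein Hspa1b (3.45) and the transcription factor Maff (3.34). Acot5 and Hspa1b have near-identical relatives, so reads between the copies are uncertain. Without WT_cold replicate 4 the change of Dgkg was 2.67, and without WT_cold replicate 1 that of Hspa1b was 2.82. With the muscle marker mean as a term Dgkg was 3.21 and Mfsd2a 6.15, and with unstranded counts the fall of Gdf5 was -5.21. The leading genes that fell were the growth factor Gdf5 (-4.17), Abhd1 (-3.67, or -3.02 without WT_RT replicate 1 and -3.05 with the replicate block), the lactate receptor Hcar1 (-3.37), the apelin receptor Aplnr (-3.18), the Wnt pathway gene Frat1 (-3.05) and the sarcomere gene Myom3 (-2.96). They also included Trarg1 (-2.86), which takes part in glucose transporter traffic, the nicotinic acid receptor Hcar2 (-2.79), the muscle glycogen phosphorylase Pygm (-2.71) and the vessel ligand Angpt1 (-2.67). Hcar1 fell from 75.3 ± 20.2 to 7.3 ± 3.32 CPM and Trarg1 from 192 ± 42.6 to 26.3 ± 9.01 CPM. Pygm was not called with the skeletal muscle marker mean as a term (adjusted p = 0.0915), and its change was -1.83 without WT_RT replicate 1.

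Of 31 gene lists fixed before the data were examined, 4 were called higher in the cold in WT, all by the camera test with a preset correlation. Heat shock proteins, the cell's folding helpers, rose in 15 of 16 members (15 adjusted over the list alone), including Hsph1 (2.75), Hspa8 (1.94) and Dnaja1 (1.73); the list had adjusted p = 1.81e-11, or adjusted p = 0.197 with an estimated correlation. Immediate early genes of cyclic AMP signalling, the messenger of adrenergic stimulation, rose in 16 of 20 members (16 adjusted over the list alone), including Fosl2 (2.38) and Per1 (2.55), with adjusted p = 5.57e-07, or adjusted p = 0.411 with an estimated correlation. Glucocorticoid-responsive genes rose in 14 of 16 members and fell in 1 (the same counts adjusted over the list alone), with Cdkn1a (2.20) and Errfi1 (1.29) rising and Angptl4 falling (-0.95); adjusted p = 5.29e-05, or adjusted p = 0.204 with an estimated correlation. Glucose uptake and glycolysis genes rose in 16 of 21 members and fell in 2 (the same adjusted over the list alone), including the glucose transporter Slc2a1 (1.22) and the falling Pdk2 (-0.73); adjusted p = 0.00157, or adjusted p = 0.615 with an estimated correlation. No list call in any of the 5 comparisons held with an estimated correlation.

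Other lists of fat metabolism moved both ways in WT and were not called. Thermogenic and brown adipocyte genes rose in 8 of 20 members and fell in 8 (the same adjusted over the list alone; camera adjusted p = 0.316), with the regulators Ebf2 (-1.12) and Esrrg (-1.35) and the beta 3 adrenergic receptor Adrb3 (-0.70) among those that fell. Secreted factors rose in 9 of 15 and fell in 4 (the same over the list alone; 0.155 adjusted), including Metrnl (1.36), Fgf9 (3.32) and Fgf21 (2.88). Lipolysis and fatty acid uptake genes rose in 7 of 19 and fell in 9, fatty acid oxidation genes in 4 and 5 of 22 (2 and 5 adjusted over the list alone), fatty acid and triglyceride synthesis genes in 3 and 6 of 20 (3 and 5), cholesterol synthesis genes in 4 and 7 of 20 (5 and 8) and mature adipocyte genes in 3 and 9 of 20. Lpl, the lipase that frees fatty acids for uptake, rose by 0.85, the triglyceride synthesis enzyme Dgat1 rose by 1.18 and the lipid regulator Srebf1 fell by 2.25. C/EBP family and adipogenic factors rose in 6 of 19 and fell in 6 (7 and 6), with Cebpd up (1.19) and Stat5a down (-2.23).

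Among stress and mitochondrial lists in WT, unfolded protein response genes rose in 10 of 21 and fell in 6, with the chaperone Hspa5 up (0.88) and Xbp1 down (-1.17). Clock genes rose in 8 of 19 and fell in 7 (8 and 8 adjusted over the list alone), hypoxia and angiogenesis genes in 7 and 6 of 16, and acute phase genes in 6 and 1 of 15. TCA cycle genes rose in 3 of 19 and fell in 2 (2 and 0), nuclear-encoded respiratory chain genes rose in 6 of 28 (5), led by Cycs (0.59), and mitochondrially encoded ones fell in 4 of 13 (3), none of which held in every alternative. The calls of mt-Nd6 (adjusted p = 0.0897), mt-Atp8 (0.573) and mt-Cytb (0.0847) ended with unstranded counts, and mt-Cytb was called only without WT_RT replicate 1 among the 10 left-out libraries (0.0528 to 0.197 without the others). The largest change, of mt-Nd3, became -0.60 without WT_RT replicate 4 (adjusted p = 0.0524). Proliferation genes fell in 2 of 18 (0). Extracellular matrix genes rose in 6 of 20 and fell in 1 (5 and 1; camera adjusted p = 0.0641), led by the basement membrane collagens Col4a1 (1.52) and Col4a2 (1.28). In the clock, hypoxia, proliferation, smooth muscle and fibroblast lists the median, mean and test differed in sign, and in the other 4 comparisons they differed only in lists that were not called.

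Markers of other cells also moved in WT. Skeletal muscle markers fell in 17 of 18 members (18 adjusted over the list alone), with a median of -5.12 and camera adjusted p = 0.133; Eno3 fell by 2.57, or 1.80 without WT_RT replicate 1. Lymphocyte markers fell in 6 of 13 (6), including the B cell genes Ms4a1 (-2.26) and Cd79a (-1.59). Macrophage markers rose in 3 of 15 and fell in 1 (2 and 0), endothelial markers rose in 6 of 14 and fell in 4, smooth muscle markers rose in 2 of 12 and fell in 4, and fibroblast markers rose in 2 of 14 and fell in 1. White adipocyte markers fell in 3 of 7 (2), Schwann cell markers in 1 of 8, and none of the 7 erythrocyte markers passed, nor any of the 4 tested neutrophil markers, too few for a list test. The smallest camera adjusted p among these lists was the 0.133 of muscle.

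The comparison of KO_cold with KO_RT asks how brown fat without C/EBP beta responds to the same cold. Nr4a3, an orphan nuclear receptor, rose 49.01-fold from 8.72 ± 7.47 to 431 ± 80.1 CPM (adjusted p = 7.34e-08), or 6.29 on the log2 scale in place of 5.61 without KO_RT replicate 1. Tbx21, the transcription factor T-bet, rose 37.7-fold from 0.997 ± 0.134 to 37.9 ± 3.34 CPM (adjusted p = 7.52e-08). Hmox1 rose 23.7-fold, from 14.4 ± 8.18 to 342 ± 46 CPM (adjusted p = 3.28e-09), and Ucp1 rose from 5967 ± 862 to 12979 ± 725 CPM (1.12 ± 0.116, adjusted p = 4.47e-08). For these 4 genes all 5 KO_cold libraries lay above all 5 KO_RT libraries. The rule for leading genes required this of Nr4a3, Tbx21 and Hmox1. In all, 4195 genes rose and 4824 fell, 59.2% of those tested, of which 759 rose and 1524 fell at least 2-fold.

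The other genes that led the rise in KO were the ketone body enzyme Bdh1 (5.48), Dgkg (5.46), Mfsd2a (4.86, or 6.18 without KO_RT replicate 3), Atf3 (4.52), Hspa1b (22.6-fold), the immediate early gene Arc (4.21) and Nr4a1 (4.07). All 10 genes that led the fall were genes of skeletal muscle contraction or energy supply, and muscle markers varied widely among the RT libraries. Myh4, Ckm and Xirp2 had 0 counts in KO_cold, which against a floor of 3 counts over the group (0.0197 CPM) made them at least 4170-fold, 1200-fold and 531-fold lower than in KO_RT. Pvalb and Mybpc1 had 1 and 3 counts in KO_cold, and Tnnt3 (-9.63), Atp2a1 (-9.20), Actn3 (-7.66), Tnni2 (-7.59) and Ttn (-7.53) had more. With the muscle marker mean as a term these changes shrank, to -2.87 for Tnnt3, -2.46 for Atp2a1 and -1.41 for Tnni2, and the rises were 4.52 for Dgkg and 5.80 for Mfsd2a. With unstranded counts Atp2a1 was -7.89, Actn3 -6.13 and Ttn -5.82. The calls of Actn3 (adjusted p = 0.173), Ttn (0.23) and Mybpc1 (0.0534) ended with the muscle marker mean as a term. Of the genes that led the fall, all but Mybpc1 and Xirp2 are in the list whose mean is that term. Their shrinking with it was thus largely built in and says nothing about its cause. Without KO_RT replicate 4 and without KO_cold replicate 5 the change of Ttn was -6.88 and -8.45.

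In KO, 7 lists were called by camera. Heat shock proteins rose in 15 of 16 members (15 adjusted over the list alone), led by the cochaperone Bag3 (2.88), with adjusted p = 5.5e-15, or adjusted p = 0.0771 with an estimated correlation. Immediate early genes rose in 17 of 20 and fell in 1 (the same over the list alone), including Nr4a2 (3.80) and Junb (1.92), with adjusted p = 4.36e-09, or adjusted p = 0.18 with an estimated correlation. Glucocorticoid-responsive genes rose in 13 of 16 and fell in 1 (adjusted p = 0.000242, or adjusted p = 0.18 with an estimated correlation). Fatty acid and triglyceride synthesis genes fell in 13 of 20 and rose in 2 (14 and 2 adjusted over the list alone), including Srebf1 (-3.04), Fasn, the fatty acid synthase (-1.47), and Acly (-1.81); adjusted p = 0.0226, or adjusted p = 0.917 with an estimated correlation. Glycolysis genes rose in 12 of 21 and fell in 2 (adjusted p = 0.0339, or adjusted p = 0.917 with an estimated correlation), and matrix genes rose in 6 of 20 and fell in 1, led by Col4a1 (1.84; adjusted p = 0.0326, or adjusted p = 0.917 with an estimated correlation). Skeletal muscle markers fell in 16 of 18 (17 adjusted over the list alone), with a median of -7.05, also with the 2 members at 0 counts set to their bounds (adjusted p = 0.0339, or adjusted p = 0.953 with an estimated correlation). With the muscle marker mean as a term, the calls of fatty acid and triglyceride synthesis (adjusted p = 0.0877), extracellular matrix (0.195) and skeletal muscle markers (0.907), whose own mean is that term, ended. Endothelial markers, not called as a list (adjusted p = 0.133), rose in 8 of 14 and fell in 4 (the same adjusted over the list alone), and their mean log2 CPM per library was 5.5 in KO_RT and 5.81 in KO_cold (exact 2-sided permutation p = 0.00794, n = 5 per group, adjusted p = 0.0706).

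The responses to cold in WT and KO resembled each other. Across the 15233 genes, which are not independent replicates, the log2 changes had a Pearson correlation of 0.889 and a Spearman correlation of 0.878. Of 7326 genes called in both genotypes, 7302 (99.7%) moved the same way, 3482 up (1101 by chance for independent sets) and 3820 down (1456 by chance). Genes that rose in both included Hmox1, Dio2 (4.03 in KO), Ppargc1a (3.78 in KO) and Dgat1 (1.39 in KO), and genes that fell in both included Cebpa, Stat5a (-2.98 in KO) and Hcar1. With no expression filter the correlation was 0.428.

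**Figure D3:**
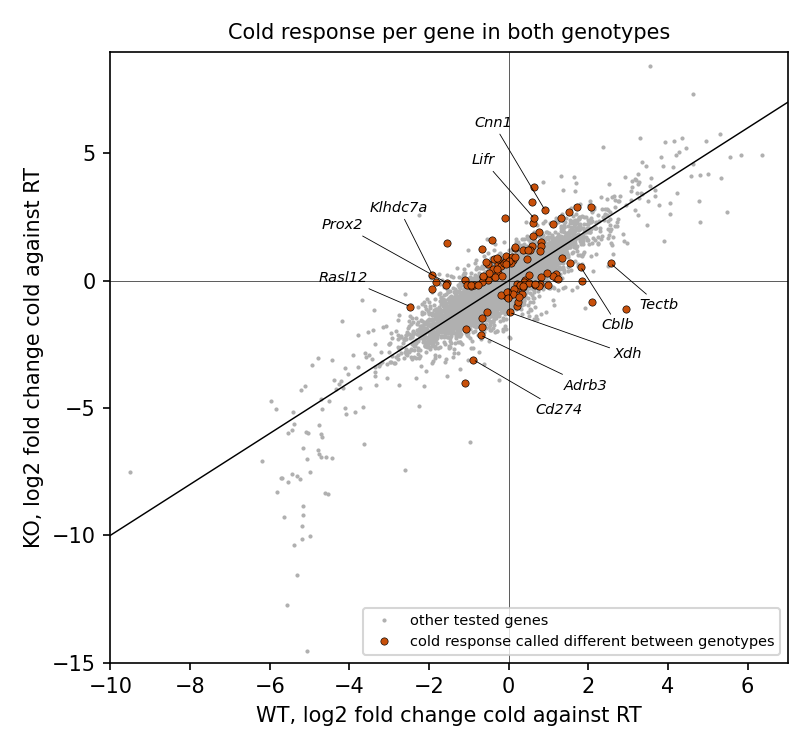
Log2 change by cold in KO against that in WT, 1 point per tested gene; the diagonal is an equal response, and the genes whose response differed between genotypes are marked, 10 of them by name. Most genes lie along the diagonal (Pearson correlation 0.889), with Klhdc7a above it and Cd274 below it.

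The comparison of KO_RT with WT_RT asks what C/EBP beta does in brown fat that is not stressed. St3gal5, the synthase of the ganglioside GM3, fell in the knockout from 82.2 ± 15.5 to 20.6 ± 6.32 CPM (adjusted p = 4.23e-05). Trib1, a pseudokinase that brings C/EBP proteins to degradation, fell from 85.1 ± 12.2 to 32.8 ± 5.25 CPM (-1.37 ± 0.128, adjusted p = 1.18e-06). Il1rn, the interleukin 1 receptor antagonist, rose from 2.21 ± 0.967 to 8.97 ± 2.9 CPM (2.02 ± 0.264, adjusted p = 9.77e-05). For these 3 genes the 5 KO_RT libraries did not overlap the 5 WT_RT libraries, which the rule for leading genes required. In all, 210 genes were higher and 201 lower in KO, 2.7% of those tested, of which 65 were higher and 51 lower at least 2-fold. The 411 genes became 267 without WT_RT replicate 5 and 269 without KO_RT replicate 4, and DESeq2 called 629.

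Other leading genes higher in KO at RT were Mc5r (2.35), H2-Q10 (2.06), Adprhl1 (1.98), Pgm5 (1.90), the paraoxonase Pon1 (1.56), the kininogen Kng2 (1.54), Tmem189 (1.53) and the prostaglandin D synthase Ptgds (1.44). Tmem189 overlaps Cebpb on the opposite strand, and H2-Q10 and Kng2 have near-identical relatives, so their reads are uncertain. Mc5r was not called without KO_RT replicate 4 (adjusted p = 0.0577), and Ptgds not without WT_RT replicate 3 (0.0513), 4 (0.0529) or 5 (0.0593). Adprhl1 was not called without WT_RT replicate 1 (0.0675), 3 (0.0653) or 4 (0.0717), nor without KO_RT replicate 1 (0.0574), 2 (0.0734) or 3 (0.0541). Beside Cebpb, the other leading genes lower in KO were Tmem56 (-2.06), Myrip (-1.92), the tight junction gene Cldn1 (-1.90), the imprinted gene Peg3 (-1.73), the fatty acid elongase Elovl3 (-1.68), the proteoglycan Gpc1 (-1.60) and the cytokine signal inhibitor Socs2 (-1.17). Cldn1 (adjusted p = 0.0668) and Elovl3 (0.112) were not called with only the groups compared in the fit. Socs2 was not called without WT_RT replicate 2 (0.0634), 3 (0.0512) or 5 (0.0856), nor without KO_RT replicate 1 (0.0764), 2 (0.051), 3 (0.0576), 4 (0.0577) or 5 (0.0671). With no expression filter Adprhl1 (0.0688), Ptgds (0.0632) and Socs2 (0.0648) were not called, nor Adprhl1 (0.0519) and Ptgds (0.0582) with both intermediate WT libraries left out.

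At RT, 10 lists were called between KO and WT, each with few members passing. Extracellular matrix genes were higher in 2 of 20 members (7 adjusted over the list alone), led by Col15a1 (0.43 ± 0.0845), with adjusted p = 7.49e-06, or adjusted p = 0.533 with an estimated correlation. Fibroblast and progenitor markers were higher in 3 of 14 (4), led by Smoc2 (0.41), with adjusted p = 0.000321, or adjusted p = 0.533 with an estimated correlation. Glycolysis genes were higher in 2 of 21 (9 higher and 1 lower adjusted over the list alone), led by the hexokinase Hk1 (0.58), with adjusted p = 0.000321, or adjusted p = 0.596 with an estimated correlation. Lipolysis and uptake genes were lower in 3 of 19 (3), led by Lpl (-0.64 ± 0.104), with adjusted p = 0.0068, or adjusted p = 0.596 with an estimated correlation. The list of C/EBP and adipogenic factors was lower (adjusted p = 7.49e-06, or adjusted p = 0.153 with an estimated correlation), and its only member past the test was Cebpb itself (1 higher and 2 lower adjusted over the list alone). Its median was -0.0142 against a mean of -0.426, and it was not tested without Cebpb. White adipocyte markers were lower in 1 of 7 (2), the amino acid transporter Slc7a10 (-0.81), with adjusted p = 0.0406, or adjusted p = 0.597 with an estimated correlation. Slc7a10 was not called without WT_RT replicate 1, 2 or 5 or KO_RT replicate 1, 3, 4 or 5 (adjusted p from 0.0615 to 0.0932). Without KO_RT replicate 4 the fibroblast markers Pdgfra (adjusted p = 0.104) and Dcn (0.115) and the matrix gene Mmp2 (0.0912) were not called. Pdgfra also ended without WT_RT replicate 1, 2 or 5 or KO_RT replicate 1 or 3, Dcn without WT_RT replicate 2, 3 or 5 or KO_RT replicate 1 or 5, and Mmp2 without WT_RT replicate 1, 2 or 4 or KO_RT replicate 3 or 5. Abhd5 was not called without WT_RT replicate 5 (0.0667) or KO_RT replicate 5 (0.0536), nor Pkm without KO_RT replicate 2 (0.05).

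The 4 other list calls at RT rested on no gene that passed, neither over all genes nor adjusted over the list alone. Fatty acid and triglyceride synthesis (adjusted p = 0.000366, or adjusted p = 0.597 with an estimated correlation) and cholesterol synthesis (adjusted p = 0.0134, or adjusted p = 0.597 with an estimated correlation) were called higher. Nuclear-encoded respiratory chain genes were called higher (adjusted p = 0.0406, or adjusted p = 0.852 with an estimated correlation) and endothelial markers lower (adjusted p = 0.0436, or adjusted p = 0.787 with an estimated correlation). With both intermediate WT libraries left out, the calls of cholesterol synthesis (adjusted p = 0.188), nuclear-encoded chain genes (0.39) and endothelial markers (0.455) ended, and the latter 2 also ended with the muscle marker mean as a term (0.114 each). The call of C/EBP and adipogenic factors ended with no expression filter (0.0899). Thermogenic genes were lower in 3 of 20 members, Elovl3, Dio2 (-1.14) and Zic1 (-0.50), with Ucp1 at 6372 ± 1379 CPM in WT and 5967 ± 862 in KO. Dio2 was not called without WT_RT replicate 4 (adjusted p = 0.0631) or 5 (0.0711) or KO_RT replicate 2 (0.0561), nor with the replicate block (0.0508), no expression filter (0.0579), only the groups compared (0.143) or both intermediate WT libraries left out (0.0574). Zic1 was called only without WT_RT replicate 2 or 4 among the 10 left-out libraries, with adjusted p from 0.0513 to 0.143 without the others, and not with the muscle marker mean as a term (0.0504) or only the groups compared (0.0515). The secreted factor Bmp8b was higher by 3.96 ± 0.646 (adjusted p = 0.00129), at 1.07 ± 0.454 CPM against 0.0671 ± 0.0588 in WT. Skeletal muscle markers had 0 members called at RT, and no member of the immediate early or heat shock lists was called.

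The comparison of KO_cold with WT_cold asks what C/EBP beta does in stressed brown fat. Trib1 stood at 28.3 ± 4.99 CPM in KO against 145 ± 17.9 in WT (-2.35 ± 0.132, adjusted p = 4.6e-10), and Cd274, the immune checkpoint ligand PD-L1, at 11.3 ± 3.57 against 65.9 ± 19.9 (-2.54 ± 0.247, adjusted p = 3.3e-06). Klhdc7a stood at 305 ± 44.6 CPM in KO against 53.2 ± 12.8 in WT (2.52 ± 0.201, adjusted p = 2.68e-07). Tbx21 was 7.26-fold higher in KO (2.86 ± 0.405, adjusted p = 0.000182), at 37.9 ± 3.34 against 5.16 ± 3.47 CPM. The 5 KO_cold libraries did not overlap the 5 WT_cold libraries in any of these 4 genes, which the rule for leading genes required. In all, 534 genes were higher and 639 lower, 7.7% of those tested, of which 115 were higher and 111 lower at least 2-fold. Of the genes called at RT, 87 were also higher in the cold (7.36 by chance for independent sets) and 110 also lower (8.43 by chance).

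Further leading genes higher in KO in the cold were follistatin, Fst (2.44), Tmem189 (2.06), Pgm5 (2.03), Zdbf2 (1.98), Pon1 (1.93), Ppl (1.83) and the cytokine receptor Lifr (1.78). The leading genes lower in KO, after Cebpb, were Acot5 (-3.90), Agbl2 (-3.12), Cd274, Cldn1 (-2.48), Trib1, St3gal5 (-2.08), the myosin light chain kinase Mylk (-2.04), Tectb (-1.99) and Tmem56 (-1.89). The size of the Mylk change rested on WT_cold replicate 4, at 859 CPM: without that library it was -1.11, still called (adjusted p = 3.95e-05). The call ended with only the groups compared in the fit (adjusted p = 0.0874). Adrb3, the receptor through which noradrenaline drives heat production, was lower by -1.34 ± 0.213 (adjusted p = 0.000463), and Pparg, the master factor of fat cells that the series title names, was lower by -0.47 ± 0.0796 (adjusted p = 0.000411). Thermogenic and brown adipocyte genes were lower in 4 of 20 members and higher in 0 (4 and 1 adjusted over the list alone). As a list they were not called (median -0.0487, camera adjusted p = 0.149).

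In the cold, 8 lists were called between KO and WT. Extracellular matrix genes were higher in 7 of 20 members (12 adjusted over the list alone), including Col6a2 (0.29) and Mmp2 (0.39), with adjusted p = 6.97e-06, or adjusted p = 0.505 with an estimated correlation. Fibroblast and progenitor markers were higher in 5 of 14 (7), including Pdgfra (0.41) and Lum (0.48), with adjusted p = 0.000382, or adjusted p = 0.505 with an estimated correlation. Immediate early genes were higher in 5 of 20 and lower in 1 (6 and 1), including Nr4a2 (1.47) and Junb (0.96), with adjusted p = 0.0028, or adjusted p = 0.505 with an estimated correlation. Heat shock proteins were called higher with Bag3 (0.99) as their only member past the test (1 adjusted over the list alone; adjusted p = 0.00543, or adjusted p = 0.505 with an estimated correlation). C/EBP and adipogenic factors were lower in 4 of 19 and higher in 1 (6 and 2), with Rxra lower (-0.54) and Rxrg higher (0.43), adjusted p = 2.56e-05, or adjusted p = 0.214 with an estimated correlation. Cebpb itself (-6.23) was among the 4, the list median was -0.12 against a mean of -0.43, and the list was not tested without Cebpb. Lipolysis and uptake genes were lower in 4 of 19 (5), including the lipase activator Abhd5 (-0.70) and the droplet coat protein Plin1 (-0.41), with adjusted p = 0.0105, or adjusted p = 0.505 with an estimated correlation. Cholesterol synthesis was called lower with 0 members past the test (0; adjusted p = 0.0114, or adjusted p = 0.505 with an estimated correlation) and mitochondrially encoded chain genes higher with 0 members (3; adjusted p = 0.0105, or adjusted p = 0.505 with an estimated correlation). With both intermediate WT libraries left out the call of lipolysis and uptake genes ended (adjusted p = 0.132). Skeletal muscle markers had 0 members called, and their list means were -0.861 ± 1.52 in WT_cold and -1.77 ± 0.112 in KO_cold.

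The interaction asks which genes responded to cold differently in KO and WT. Klhdc7a (ENSMUSG00000078234.6, GRCm38 chromosome 4, 139960220 to 139968026) fell with cold in WT from 202 ± 40.6 to 53.2 ± 12.8 CPM and stood at 259 ± 73.2 and 305 ± 44.6 CPM in KO, a difference in response of 2.16 ± 0.272 (adjusted p = 0.000853). Cd274 (ENSMUSG00000016496.7, chromosome 19, 29367455 to 29388095) went from 122 ± 11.1 to 65.9 ± 19.9 CPM in WT and from 97.4 ± 29.3 to 11.3 ± 3.57 CPM in KO (-2.22 ± 0.331, adjusted p = 0.00373). Adrb3 (ENSMUSG00000031489.15, chromosome 8, 27225776 to 27250616) went from 93 ± 20.5 to 57.2 ± 7.15 CPM in WT and from 99.7 ± 20.4 to 22.4 ± 7.51 CPM in KO (-1.44 ± 0.295, adjusted p = 0.0261). Tectb went from 3.11 ± 0.8 to 18.4 ± 3.62 CPM in WT and from 2.89 ± 0.61 to 4.59 ± 0.716 CPM in KO (-1.89 ± 0.249, adjusted p = 0.000722). In all, 113 genes differed in response, 65 with a higher and 48 with a lower value in KO.

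**Figure D4:**
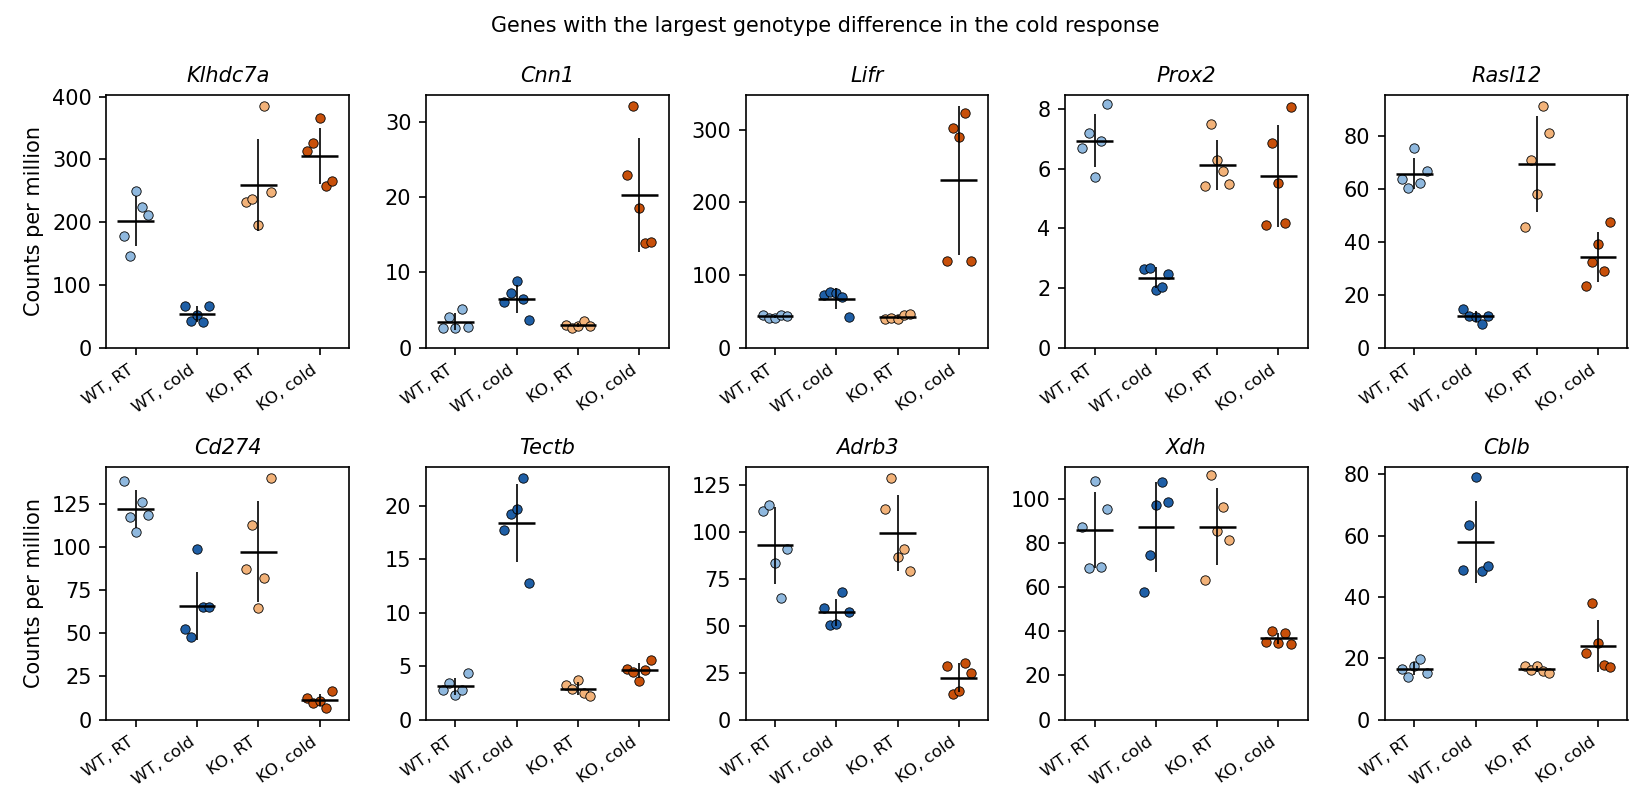
CPM of the 10 leading interaction genes in the 4 groups; points are libraries, horizontal lines are group means and vertical lines are 1 SD. Klhdc7a falls from 202 to 53.2 CPM with cold in WT and stands at 259 and 305 CPM in KO, and Cd274 falls from 122 to 65.9 CPM in WT and from 97.4 to 11.3 CPM in KO.

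The other leading genes with a higher response in KO were the smooth muscle gene Cnn1 (1.85), Lifr (1.81), the homeobox gene Prox2 (1.46) and Rasl12 (1.46), and those with a lower one were the xanthine dehydrogenase gene Xdh (-1.27) and the ubiquitin ligase Cblb (-1.27). Of the 113 genes, 28 rose with cold in WT and had a lower response in KO, 27 fell in WT and had a higher response in KO, 18 rose with a higher and 8 fell with a lower response in KO, and 32 were not called by cold in WT. WT libraries enter both the WT call and, with opposite sign, the difference, which favours the groups of 28 and 27. These counts thus show no general weakening in KO: the slope of KO on WT responses over all 15233 tested genes was 1.017. The 113 became 74 with both intermediate WT libraries left out, where Lifr (adjusted p = 0.0648), Xdh (0.0633) and Adrb3 (0.0754) were not called, and DESeq2 called 269. With no expression filter Cnn1 (0.0632), Adrb3 (0.0643) and Cblb (0.0643) were not called. Adrb3 was not called without WT_RT replicate 3 (0.0516), WT_cold replicate 4 (0.054) or KO_RT replicate 2 (0.053). Cblb was not called without WT_RT replicate 1 (0.0516) or 5 (0.0521), KO_RT replicate 1 (0.0539), 2 (0.0531) or 3 (0.0554), or KO_cold replicate 1 (0.0528).

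For the interaction, 9 lists were called. Heat shock proteins had a higher response in KO, with Bag3 (1.18 ± 0.212, adjusted p = 0.012) as the only one of 16 members past the test (1 adjusted over the list alone; list adjusted p = 0.000107, or adjusted p = 0.473 with an estimated correlation). Immediate early genes had a higher response with 1 of 20 members past the test (3), Junb (1.15; list adjusted p = 0.00407, or adjusted p = 0.706 with an estimated correlation), and smooth muscle markers had a higher response with Cnn1 alone of 12 (1 higher and 1 lower; adjusted p = 0.0172, or adjusted p = 0.473 with an estimated correlation). Junb was not called without WT_RT replicate 1, 3 or 4, WT_cold replicate 3, 4 or 5, KO_RT replicate 3, 4 or 5, or KO_cold replicate 2, 3 or 5 (adjusted p from 0.0518 to 0.0731), nor with the replicate block (0.068), the muscle marker mean as a term (0.0605), no expression filter (0.0934) or both intermediate WT libraries left out (0.123). The call of Cnn1 ended with no expression filter (0.0632). The other calls rested on 0 members past the test over all genes. Fatty acid and triglyceride synthesis genes had a lower response in KO (0 higher and 1 lower adjusted over the list alone), with a median of -0.73 and adjusted p = 2.24e-07, or adjusted p = 0.473 with an estimated correlation. Cholesterol synthesis genes had a median of -0.33 (0; adjusted p = 3.11e-07, or adjusted p = 0.378 with an estimated correlation). Nuclear-encoded chain genes were lower (0; adjusted p = 0.00685, or adjusted p = 0.961 with an estimated correlation) and mitochondrially encoded ones higher (0; adjusted p = 0.0167, or adjusted p = 0.473 with an estimated correlation). Endothelial markers were higher (0; adjusted p = 0.0167, or adjusted p = 0.801 with an estimated correlation) and skeletal muscle markers lower (0; adjusted p = 0.0221, or adjusted p = 0.961 with an estimated correlation).

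Of these 9 interaction calls, 5 ended with both intermediate WT libraries left out: immediate early genes (adjusted p = 0.135), mitochondrially encoded chain genes (0.0713), endothelial markers (0.292), smooth muscle markers (0.087) and skeletal muscle markers (0.0828). With the muscle marker mean as a term, nuclear-encoded chain genes (0.0621), endothelial markers (0.129) and skeletal muscle markers (0.77), whose own mean is that term, ended. With the replicate block skeletal muscle markers (0.0623) ended. The calls of heat shock proteins, fatty acid and triglyceride synthesis and cholesterol synthesis held in these 3 alternatives.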

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

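The tests of extra gene copies, split reads, muscle in the sample, muscle genes of fat cells and exchanged labels were chosen only after the result was seen, and the test of muscle genes of fat cells was revised after its first value was seen, while the splits and the test of mixed RNA were planned. For the 4 comparisons of 2 groups, refits of 100 of the 126 possible splits of the libraries excluded chance for the counts of called genes. These refits held only the groups compared, so their counts differ from those of the report, which come from all 20 libraries. For cold in WT 1 of 100 splits, the real one, reached 7935 genes, and the highest other called 1440, a split that exchanged WT_RT replicate 4 with WT_cold replicate 5. For cold in KO only the real split, 1 of 100, reached 8720 genes, with 3 in the highest other. For the knockout at RT 1 split reached 419 genes (highest other 31), and for the knockout in the cold 1 split reached 900 (highest other 10). For the interaction, 100 of 31752 possible splits were refitted. There 2 of the 100 reached 113 genes, the real one and 1 other that called 148, more than the real split. That other split exchanged WT_RT replicate 5 with KO_RT replicate 5 and kept all other labels. Because genotypes were exchanged within each temperature, a split can turn the knockout's effect at 1 temperature into interaction. The splits thus do not test chance alone, and they cannot exclude it for this count.

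Among 358 groups of 5 libraries over 111 measures, 26 held a library far from the other 4 by Dixon's test (critical value 0.71), against 17.9 by chance. In mean log2 CPM, WT_cold replicate 4 stood at 8.04 for thermogenic genes (others 7.77 to 7.83), WT_RT replicate 5 at 3.1 for secreted factors (2.93 to 2.97), and WT_cold replicate 3 at 8.39 for mitochondrially encoded chain genes (8.03 to 8.04). WT_cold replicate 5 stood at 4.01 for hypoxia genes (4.34 to 4.4), 0.79 for neutrophil markers (-1.47 to -0.97) and 5.45 for erythrocyte markers (2.81 to 3.1). KO_RT replicate 2 stood at 3.51 for macrophage markers (2.89 to 2.98) and KO_RT replicate 1 at 5.34 for smooth muscle markers (5.18 to 5.22). In KO_cold replicate 2, 1.09% of reads lay in more than 1 gene (others 1.03% to 1.05%).

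Single genes far from the rest of their group were often in WT_cold replicate 5, an intermediate library: Cebpa at 262 CPM (others 76.6 to 120), Abhd1 at 0.954, Frat1 at 1.45, Trarg1 at 42.1 and Lifr at 41.5 (69.9 to 76.5). WT_cold replicate 4 held Dgkg at 22.4 CPM (0.93 to 4.18) and Mylk at 859 CPM (119 to 226). KO_RT replicate 4 held Mc5r at 35.8, Myrip at 2.28 and Klhdc7a at 385 CPM (195 to 247), KO_RT replicate 3 Mfsd2a at 22.5 CPM (0.963 to 3.34) and KO_RT replicate 1 Il1rn at 14 CPM (6.65 to 8.4). WT_RT replicate 5 held Tmem189 at 24 CPM (16.5 to 18.5) and WT_RT replicate 3 St3gal5 at 55.4 CPM (83.6 to 93.8). In KO_cold, Tbx21 stood at 32 CPM in replicate 5 (38.3 to 40.4), Ttn at 0.148 CPM in replicate 5 and Pvalb at 0.0392 CPM in replicate 2.

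The genes whose cold response differed between genotypes, 113 in all, were led by Klhdc7a (2.16), Cnn1 (1.85), Lifr (1.81), Prox2 (1.46) and Rasl12 (1.46), with a higher response in KO. Cd274 (-2.22), Tectb (-1.89), Adrb3 (-1.44), Xdh (-1.27) and Cblb (-1.27) led those with a lower one. These are the interaction tests of the report.

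Neighbours of Adipoq, chosen after their values were seen, were higher in the knockout at both temperatures: Kng1 (6.26 at RT, 6.49 in the cold), Kng2 (1.54 and 1.40), Eif4a2 (0.39 and 0.54) and Rfc4 (0.67 and 0.56), while Adipoq itself stood at -0.01 and -0.04. Reads split between near-identical copies were tested by whether Eif4a2 or Rfc4, no copies of the kininogens, were higher, and Eif4a2 was, by 0.544 in the cold. Both genes had been taken into the pattern because they were higher. The outcome was thus fixed in advance, and the test decides nothing about split reads of Kng1 and Kng2. A candidate explanation is extra gene copies brought in with a transgene made from the Adipoq region. For it, 3 of 7 tested genes within 100 kb were called at both temperatures, a number reached in 2 of 15209 other windows (0.0132%). These left out the windows around Cebpb, where 4 of 4 tested neighbours were called, and around the neighbours of both genes. The Adipoq window was picked because its genes were higher, so this share is no measure of chance. The labels name no Cre driver, and the bound set for this test was 4 genes, so extra copies and an effect of C/EBP beta on this region cannot be told apart: the transgene, if there is one, goes with the genotype.

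Skeletal muscle markers were lower in the cold libraries. Muscle dissected with some fat pads may be the source, since among the RT libraries the markers rose and fell together within groups, with a median Spearman correlation of 0.976, against at most 0.152 in 1000 random lists. Their mean log2 CPM ranged from -1.8 to 5.86 at RT and from -2.06 to 1.04 in the cold, and Acta1 from 0.129 to 198 CPM at RT, while Myl1 (6569 counts) and Mb (1433 counts) were still present in KO_cold. That cold lowers muscle genes which fat cells express is left open: 1 of the 9 RT libraries other than WT_RT replicate 4 lay within the range of the cold libraries, and muscle content went with temperature. As first run, the test counted all 10 RT libraries, of which 2 lay within that range, enough under its bound to argue against this explanation; WT_RT replicate 4, an intermediate library, was left out after that value was seen.

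WT_RT replicate 4 and WT_cold replicate 5 lay between the temperatures on the first principal component. RNA of the other temperature mixed into the library is argued against as the whole cause: the shares from rising and from falling genes differed by at least 0.329 in both (0.0401 and 0.369 in WT_RT replicate 4, 0.507 and 0.0815 in WT_cold replicate 5), though differences of up to 0.204 occurred in other WT libraries. Exchanged labels of the 2 libraries need shares of the other temperature near 1 and are argued against by shares of 0.0969 and 0.289 over rising and falling genes together, although the rising genes alone gave 0.507 in WT_cold replicate 5. On the first principal component each library lay on the side of its own label (-23.4 and 26.6). A weaker or shorter exposure to cold, or handling of single animals, was not tested.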

How the results depend on the processing

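The alternative without both intermediate WT libraries was added after the data were seen, and sex as a term was not run because all libraries were male-like. Of 13618 values of named genes, 13039 kept their status as called or not called, 442 lost the call, 136 gained it and 1 reversed: Notch3 for cold in KO, at 0.0175 with unstranded counts (adjusted p 0.902). A reversal was counted only where the gene was called in the report or in the alternative. Changes of sign in genes called in neither were not counted. For the knockout at RT, 411 genes were 629 with DESeq2, 267 without WT_RT replicate 5 and 269 without KO_RT replicate 4, and at most 356 without any other library. For the interaction, 113 genes were 269 with DESeq2 and 74 with both intermediate WT libraries left out. The correlation of the cold responses was 0.428 with no expression filter. With an estimated correlation, 0 lists were called in each of the 5 comparisons. For cold in WT, 4 called lists were 9 with no expression filter and 6 with both intermediate WT libraries left out, and for the knockout in the cold 8 were 16 with no expression filter. With the skeletal muscle marker mean as a term, 7 lists for cold in KO were 4 and 9 for the interaction were 6, and with both intermediate WT libraries left out the latter were 4. The cause was not tested. Libraries of the same replicate number had a median correlation of 0.0147 (7 of 30 above 0.1), against -0.00732 for different numbers. Of 20 libraries, 6 correlated best with one of their own number. A weak pairing by number is thus not excluded. With the replicate block 8491, 8958, 383, 1078 and 94 genes were called for the 5 comparisons.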

Other observations

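The tests of ribosome biogenesis and imprinted genes, and the bounds of the latter, were chosen only after the result was seen. Genes of ribosome biogenesis, chosen after their values were seen, rose in 21 of 24 members and fell in 2 in both WT and KO, with medians of 0.609 and 0.745 (larger camera adjusted p = 2.99e-12, or adjusted p = 0.0138 and 0.0115 with an estimated correlation). These were adjusted over the 2 tests alone, not over the 30 lists of a comparison, and do not compare with the list values. For heat shock proteins camera with an estimated correlation gave unadjusted p = 0.00657 in WT and 0.00257 in KO, which were not called over the 30 lists. Nop2 (1.34 in WT, 1.46 in KO) and Rrp12 (1.31 and 1.46), which process ribosomal RNA, and Polr1a (1.01 and 1.15), a subunit of RNA polymerase I, rose, while Dkc1 fell (-0.84 and -0.60). Cold may raise the making of ribosomes in brown fat of both genotypes, a hypothesis found and tested on the same data.

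Imprinted genes, chosen after their values were seen, were called in the knockout in 6 of 31 cases (19.4%), against 1379 of 15202 other genes (9.07%; Fisher's exact 2-sided p = 0.0573, odds ratio 2.41, interval 0.806 to 6.02). At RT Peg3 (-1.73), Usp29 (-2.92), Zim1 (-0.73) and Magel2 (-3.01) were lower and Nap1l5 (0.85) was higher, and in the cold Magel2 was lower (-3.67) and Zdbf2 higher (1.98). Whether imprinted genes are called more often than others cannot be told apart from chance with 31 genes, which the test takes as independent.

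Next to Cebpb, all 4 genes tested were higher in the knockout at both temperatures, chosen after their values were seen: Tmem189 (1.53 at RT, 2.06 in the cold), A530013C23Rik (2.07 and 2.03), Gm14321 (3.84 and 2.67) and 9230111E07Rik (2.11 and 2.91). Tmem189 overlaps Cebpb on the opposite strand. No test separated an effect of the altered locus from an effect of the missing protein.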
